A study of Mus musculus with 446 samples.

How the data were processed

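RNA from liver, skeletal muscle and abdominal adipose tissue of male Diversity Outbred mice on a control or high-fat diet was sequenced on MiSeq from stranded total RNA libraries, per the labels' protocols. The submitters' processing notes name FastQC, Trim Galore 0.4.4 and Bowtie 1.2.2. The quantifier, genome build and annotation are not given in the sources used here. The deposited values are TPM: they are not whole numbers, and each column of the liver and muscle tables sums to 1000000 over 47643 genes, ribosomal RNA-like genes included, although the tables carry the word counts in their names. The adipose table holds 2728 complete genes on the same scale and 1 incomplete line, which was left out. The analysis had been planned for counts. With TPM the tests were made with limma on log2 values instead, and the count-based tests were not run. TPM keep no depth, so the depth of each library is unknown and no counting interval can be given. Liver libraries held a median of 12.8% and at most 97.7% of TPM on ribosomal RNA-like genes, and muscle libraries 1.74% and at most 94.5%. The share on nuclear protein-coding genes did not pass a two-sided permutation test between diets in liver (p = 0.906) or muscle (p = 0.216).

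Samples were grouped by the tissue and diet in the labels. The labels of 11 liver libraries carry a second number after the mouse number. These libraries were kept in the main analysis and left out in an alternative. Ensembl gene IDs were matched to symbols and gene types of GENCODE release M21, with 99.9% matched in adipose tissue and 99.1% in liver and muscle. Each library was scaled by an unweighted trimmed mean of log ratios to the median library over nuclear protein-coding genes other than Lars2, with 0.3 of the ratios and 0.05 of the levels trimmed at each end. Scale factors spanned 0.0489 to 1.62 in adipose tissue, 0.0149 to 2.39 in liver and 0.0514 to 2.09 in muscle. A factor under 1/3 of the tissue's median was found in 18 adipose, 26 liver and 11 muscle libraries (11, 14 and 2 control against 7, 12 and 9 high-fat, two-sided Fisher's exact p = 0.323, 0.671 and 0.0558). Such libraries were kept in the main analysis and left out in an alternative. A gene was tested where its scaled TPM was at least 1 in as many libraries as 0.7 of the smaller diet group. Values were log2(scaled TPM + 1), fitted by diet with limma's lmFit and eBayes (trend and robust), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are high-fat minus control, and means and SDs are of scaled TPM over mice.

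Differences of the diet effect between tissues were tested as an interaction in a fit of the tissue pair compared, without a block, over genes tested in both. For this fit the libraries were not scaled within each tissue, which was an alternative. Its differences therefore need not equal those between the effects of the single tissues. Same-numbered samples were taken as the same mouse. This pairing was checked by correlating the deviations from the group means over 150 selected genes. On these genes the liver of a mouse correlated best with the muscle of its own number in 142 of 149 mice. Adipose tissue correlated best with liver and with muscle of its own number in 90 of 148 mice each. Among the 7 mice that did not match, 4 libraries correlated with a mouse on the other diet above any value between different mice that matched, and their labels were kept. Over all 10210 genes tested in both, the median correlation between liver and muscle of the same number was 0.119, against 0.00302 for different numbers. A fit with the mouse as block was run as an alternative. The spread was tested by limma on absolute deviations from the diet median, for genes with a mean scaled TPM of at least 5. Relations across mice used Pearson's r and Spearman's rho with 100000 permutations, two-sided.

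Gene lists of pathways and cell type markers were written from textbook knowledge before the data were examined, as were the tests, the alternative analyses and the rule for named genes. Lists with at least 5 tested members were tested with limma's camera (preset correlation 0.01), and camera with an estimated correlation and fry were alternatives. fry tests whether the members move, on balance, 1 way, and does not compare a list with other genes. The named genes per tissue were the 8 largest rises and the 8 largest falls past the threshold with a mean of at least 5 scaled TPM (planned as a count minimum), without predicted and clone names. Added to these were up to 4 members of each list with the smallest p, and Lep, Adipoq, Cidea, Cyp7a1, Pdk4 and Ucp3 in their tissues. Each interaction named the 4 largest differences in each direction, and the spread test the 5 smallest p in each direction. The rule gave 75 genes in adipose tissue, 117 in liver and 101 in muscle, of which 40, 44 and 32 are printed. Genes outside it are said to be named after their values were seen.

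The diet, interaction, spread and list tests were run on simulated data with 200 changed genes, or 3 changed lists. The simulated values were already scaled and filtered, and the scaling, the pairing and the relations across mice were not simulated. For adipose tissue 200 of 2175 genes were changed, fewer than the 1001 called in the real data. The diet test recovered 73.1% of genes changed by 0.25 on the log2 scale and 98.5% of those changed by 0.5 in adipose tissue, 52.2% and 95.5% in liver, and 70.1% and 95.5% in muscle, with 3 of 184, 6 of 169 and 3 of 179 calls false. The interaction test recovered 97.0%, 89.6% and 95.5% of differences of 0.5 between liver and adipose tissue, liver and muscle, and muscle and adipose tissue. The spread test recovered 43.3%, 5.97% and 14.9% of genes whose spread grew 1.5 times in adipose tissue, liver and muscle. camera with the preset correlation recovered 3 of 3 changed lists in each tissue but also called 2 of 8 unchanged lists in adipose tissue, 6 of 20 in liver and 4 of 18 in muscle. With an estimated correlation it recovered 3 of 3 and called 0 unchanged lists in each tissue. All members of a changed list were raised by 0.5 on the log2 scale. Recovery of lists with smaller or mixed shifts was not simulated.

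No pair of libraries within a tissue was identical (highest correlation 0.984 in adipose tissue, 0.952 in liver and 0.963 in muscle). Xist lay below the sum of Y-linked genes in all 149 liver and all 149 muscle libraries. Mouse 80 had liver and muscle libraries that held the genes of the other tissue. The labels were kept in the main analysis, and an alternative left this mouse out. Alternatives planned before the data were examined were median-of-ratios scaling, scaling within each tissue for the interaction, no filter, stricter thresholds and other pseudocounts. Also planned were the block, other set tests, other forms of the spread and relation measures, and leaving out the liver libraries with a second number. Alternatives chosen after seeing the data were a mean of at least 5 scaled TPM, the coding share as covariate, leaving out libraries of low coding share or low scale factor, leaving out mice whose tissues did not match or mouse 80, a pseudocount of 0.1, unscaled TPM and array quality weights. Each was run for the results it applies to. The work used R 4.3.3, limma 3.58.1, the R package data.table, version 1.17.8, and Python 3.11.15.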

Results

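RNA was sequenced from liver, skeletal muscle and abdominal adipose tissue of male Diversity Outbred mice, an outbred stock in which each animal carries its own mixture of founder genomes. The mice ate a control diet (10 kcal% fat) or a high-fat diet (60 kcal% fat) for 14 weeks. The 446 libraries came from 74 control and 75 high-fat mice, of which all but 1 gave 3 tissues. Adipose tissue was sequenced in 73 control and 75 high-fat mice, and liver and muscle in 74 control and 75 high-fat mice each. The design text states that expression was measured to look at variability among mice. The deposited values are TPM (length-corrected abundances that add up to the same total in every library), which keep no depth, so the depth of each library is unknown. The share of TPM on nuclear protein-coding genes had a median of 60.4% in control liver (range 0.608% to 74.6%) and 60.6% in high-fat liver (0.41% to 74.9%). In muscle it was 66.3% (6.74% to 74.1%) and 63.4% (2.54% to 76.3%). The adipose table is partial, so Lep, Adipoq and most other adipose genes were not analysed here. All fold changes below are high-fat minus control on the log2(scaled TPM + 1) scale, which understates changes of weakly expressed genes. The genome build behind the values is not given, so genes are identified by symbol and Ensembl gene ID and no positions are printed.

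The first comparison asked which genes differed by diet in abdominal adipose tissue. The macrophage genes Cd68 and Adgre1, the chemokines Ccl9 and Ccl6, 8 of 9 matrix genes and all 8 cell cycle genes rose on the high-fat diet, and all 5 genes of fatty acid synthesis, all 5 adipocyte markers and all 9 electron transport genes fell. With an estimated correlation between genes only the fatty acid synthesis list held its set test (adjusted p = 0.0225, against 0.111, 0.106, 0.106 and 0.231 for the matrix, cell cycle, adipocyte and electron transport lists), and the electron transport median was 0.06 with TPM as deposited, where that of all genes was 0.21. Cd68 (ENSMUSG00000018774), a lysosomal glycoprotein of macrophages, rose from 53.7 ± 54.5 to 168.5 ± 139.2 scaled TPM (SD, n = 73 and 75), a log2 fold change of 1.56 ± 0.17 (SE; adjusted p = 3.63e-13, limma). Cd68 lay above the control median in 71 of 75 high-fat mice. Acaca (ENSMUSG00000020532), the acetyl-CoA carboxylase that commits carbon to fatty acid synthesis, fell from 373 ± 270 to 98.1 ± 52.5 scaled TPM, a log2 fold change of -1.73 ± 0.13 (adjusted p = 5.17e-23), and 74 of 75 high-fat mice did not exceed the control median. Timp1, a metalloproteinase inhibitor, had the largest rise among the genes named by the rule, from 6.13 ± 6.54 to 30.1 ± 39.3 scaled TPM (log2 fold change 1.73 ± 0.21).

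Of the 3 macrophage markers tested in adipose tissue, 2 rose, Cd68 and the surface receptor Adgre1 (log2 fold change 1.17 ± 0.14), and Cd163 had -0.13 ± 0.08 (adjusted p = 0.171). Of 4 chemokines, Ccl9 (1.45 ± 0.16) and Ccl6 (1.05 ± 0.15) rose, while Ccl8 had 0.41 ± 0.23 and Ccl11 had 0.17 ± 0.09 (adjusted p = 0.144 and 0.115). The leukocyte genes Il7r, the interleukin 7 receptor, and Itgb2, a leukocyte integrin, rose by 1.55 ± 0.17 and 1.27 ± 0.16. No lymphocyte marker of 3 passed the test, among them Cd79a with 0.16 ± 0.13 and Lck with -0.06 ± 0.11. Of 4 endothelial markers 1 fell, Ptprb by -0.18 ± 0.06, a value that was 0.06 with TPM as deposited, where the median of all genes was 0.21, and Pecam1 had 0.03 ± 0.05 (adjusted p = 0.658). The neutrophil list had 1 tested member, Mmp9, which did not pass. Counts adjusted over the list alone were the same for these lists except that Mmp9 then passed as lower. These lists had fewer than 5 tested members and no set test.

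All 5 tested fatty acid synthesis genes fell, Acaca beside the lipogenic transcription factors Mlxipl (-0.77 ± 0.10) and Srebf1 (-0.47 ± 0.08) and the citrate carrier Slc25a1 (-0.53 ± 0.10). Their set test, limma's camera with a preset correlation, gave an adjusted p of 4.16e-05 (adjusted p = 0.0225 with an estimated correlation). All 5 tested adipocyte markers fell, with the hormone Retn at -1.27 ± 0.16, the glucose transporter Slc2a4 at -0.73 ± 0.09, the nuclear receptor Pparg at -0.48 ± 0.08 and the lipase Lpl at -0.40 ± 0.08. The adipocyte list had a camera adjusted p of 9.61e-05 (adjusted p = 0.106 with an estimated correlation). In the insulin signalling list 6 of 9 members fell, 7 when adjusted over the list alone, including the hexokinase Hk2 (-0.55 ± 0.08) and the insulin receptor Insr (-0.29 ± 0.05). Its 1 member that rose was Pdk4, an inhibitor of glucose oxidation (0.71 ± 0.15). The insulin signalling list had a camera adjusted p of 0.000993 (adjusted p = 0.106 with an estimated correlation). Pdk4 and Angptl4, a lipoprotein lipase inhibitor (0.45 ± 0.10), were the 2 of 5 fatty acid oxidation and PPAR alpha target genes that rose, and that list did not pass (camera adjusted p = 0.167).

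All 8 tested cell cycle genes rose, with Cdk1 at 0.80 ± 0.10 and Birc5 at 0.66 ± 0.11 (camera adjusted p = 3.16e-05, adjusted p = 0.106 with an estimated correlation). Of 9 matrix genes 8 rose, with Timp1, the protease Mmp14 (0.62 ± 0.08) and the collagens Col1a1 (0.59 ± 0.12) and Col6a1 (0.47 ± 0.10) in the lead (camera adjusted p = 0.000267, adjusted p = 0.111 with an estimated correlation). All 9 nuclear electron transport genes fell, among them Ndufa1 (-0.27 ± 0.05) and Cox6c (-0.27 ± 0.05), with a median of -0.18. That list had a camera adjusted p of 0.000295 (adjusted p = 0.231 with an estimated correlation). Of 8 ribosomal protein genes 7 rose, such as Rps18 by 0.15 ± 0.04 (camera adjusted p = 0.0244, adjusted p = 0.373 with an estimated correlation). Ribosomal protein genes have near-identical copies that can share reads, so these values are uncertain. Counts adjusted over the list alone equalled those over all genes for the synthesis, oxidation, adipocyte, cell cycle, matrix, electron transport and ribosomal lists. Members of the adipokine and adipose expansion list moved both ways, 3 up and 3 down of 7 (4 up and 3 down adjusted over the list alone), with the imprinted gene Peg3 up by 0.99 ± 0.14 (camera adjusted p = 0.732). The endoplasmic reticulum stress list had 4 members up and 1 down of 6, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0746). Outside these lists, Hsd11b1, the enzyme that regenerates active glucocorticoid, fell by 1.35 on the log2 scale, the proline oxidase Prodh by 1.07 and the acyltransferase Mogat1 by 1.02, while the muscle-type adenylosuccinate synthase Adssl1 rose by 1.16.

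In adipose tissue 1001 of 2175 tested genes differed by diet, 501 higher and 500 lower (limma, adjusted p under 0.05), and 91 of them by a fold of at least 1.5. With TPM as deposited the count was 317, with 300 higher and 17 lower, and the median of all genes moved to 0.21 on the log2 scale, so the directions above are relative to the scaled median. The table's sum, a stand-in for the coding share, was higher on the high-fat diet than on control (medians 15.3% and 14.5% of TPM, two-sided permutation p = 0.00035).

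**Figure D1:**
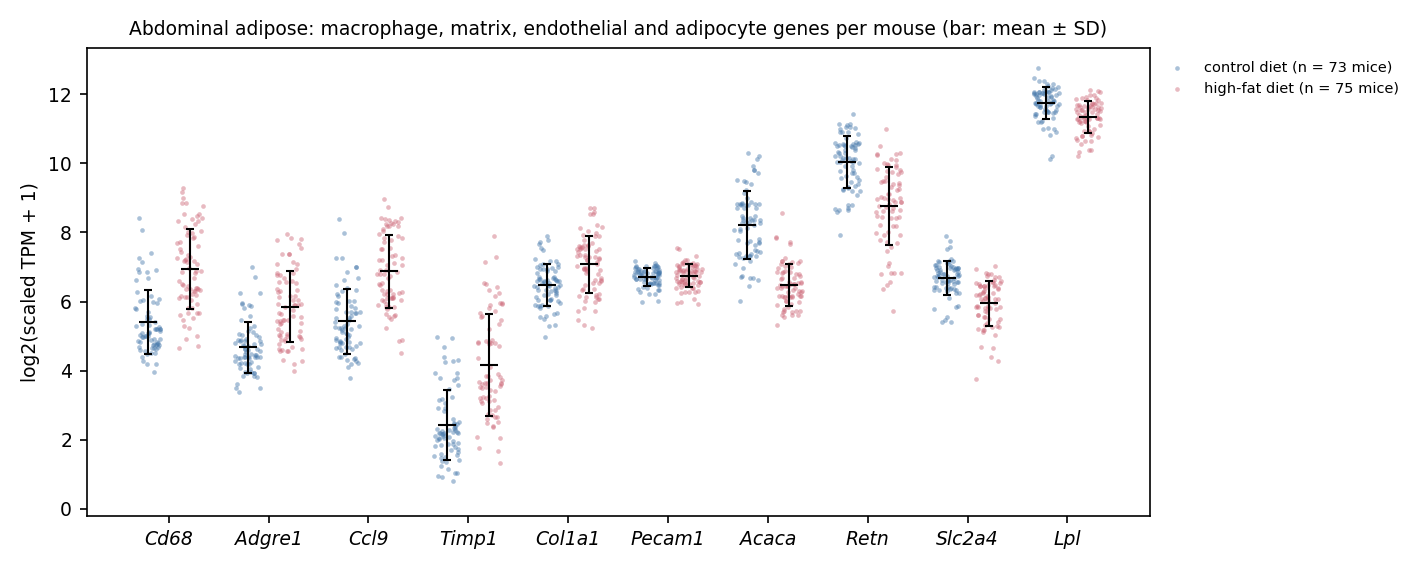
Each point is 1 mouse and gives log2(scaled TPM + 1) of 1 gene in abdominal adipose tissue, with control mice in blue and high-fat mice in red, and black bars give the mean and SD. Cd68, Adgre1, Ccl9, Timp1 and Col1a1 sit higher and Acaca, Retn, Slc2a4 and Lpl lower on the high-fat diet, and Pecam1 had a log2 fold change of 0.03.

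The second comparison asked the same in liver. Genes of fatty acid synthesis fell on the high-fat diet, with Scd1 far ahead, and genes of fatty acid oxidation rose. Scd1 (ENSMUSG00000037071), the stearoyl-CoA desaturase that makes monounsaturated fatty acids, fell from 1252 ± 693 to 107.5 ± 184 scaled TPM (SD, n = 74 and 75), a log2 fold change of -4.87 ± 0.27 (SE; adjusted p = 3.73e-35, limma). Scd1 exceeded the control median in 0 of 75 high-fat mice. The fatty acid binding protein Fabp5 fell by 2.31 ± 0.20 (adjusted p = 1.97e-19, 71 of 75 mice not above the control median). Obp2a, a lipocalin, had the largest rise among the genes named by the rule, from 2.85 ± 8.88 to 25.9 ± 55.4 scaled TPM (2.16 ± 0.30, adjusted p = 6.64e-09, 60 of 75 mice above the control median).

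Of 20 fatty acid synthesis genes in liver 17 fell, 18 when adjusted over the list alone, and none rose (camera adjusted p = 4.16e-48, adjusted p = 2.39e-06 with an estimated correlation). Besides Scd1 these included the carboxylase Acacb (-1.84 ± 0.14), the lipid droplet protein Pnpla3 (-1.46 ± 0.14), the malic enzyme Me1 (-1.42 ± 0.16), the fatty acid synthase Fasn (-1.23 ± 0.15) and the acetyl-CoA synthetase Acss2 (-1.21 ± 0.11). Of 25 fatty acid oxidation and PPAR alpha target genes 15 rose and none fell, or 17 and 1 adjusted over the list alone (camera adjusted p = 1.27e-16, adjusted p = 0.0289 with an estimated correlation). The carnitine palmitoyltransferase Cpt2 rose by 0.45 ± 0.05 and lay above the control median in 71 of 75 mice, the carnitine carrier Slc25a20 rose by 0.38 ± 0.05 and the isomerase Eci2 by 0.44 ± 0.07. Of 24 cholesterol synthesis and uptake genes 8 fell, 12 adjusted over the list alone, led by Pmvk (-0.92 ± 0.12) and Sc5d (-0.65 ± 0.09). The cholesterol list had a camera adjusted p of 1.11e-07 (adjusted p = 0.313 with an estimated correlation).

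Lipid droplet genes moved both ways, with 4 of 12 up and 1 down, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.00141, adjusted p = 0.0795 with an estimated correlation). The fat storage proteins Fitm1 and Fitm2 rose by 0.85 ± 0.17 and 0.28 ± 0.06, the fatty acid transporter Cd36 rose by 0.47 ± 0.14, and the droplet coat protein Plin3 fell by 0.27 ± 0.07. Cidea, a droplet fusion protein, did not reach the expression minimum in liver and was not tested. In the gluconeogenesis and insulin signalling list 4 of 17 fell and 1 rose, or 6 and 1 adjusted over the list alone, with Igfbp1, a liver gene repressed by insulin, at -1.11 ± 0.21 and the insulin receptor substrate Irs2 at -0.48 ± 0.09. That list had a camera adjusted p of 0.0134 (adjusted p = 0.296 with an estimated correlation). Of 16 bile acid and sterol transport genes 2 rose and 4 fell, or 3 and 6 adjusted over the list alone (camera adjusted p = 0.376). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 0.67 ± 0.18 and the phospholipid exporter Abcb4 by 0.49 ± 0.06, while the bile salt exporter Abcb11 fell by 0.38 ± 0.09. Cyp7b1 had 0.47 ± 0.17 (adjusted p = 0.0709), and without mouse 80, whose liver library held muscle genes, it had 0.56 (adjusted p = 0.00256). In the xenobiotic list 2 of 22 rose, among them the reductase Por (0.49 ± 0.14), and 1 fell, Gstm1 (-0.36 ± 0.09), with 2 up and 2 down adjusted over the list alone (camera adjusted p = 0.98).

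The circadian clock list rose in liver, with 9 of 16 members up and 2 down, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.000559, adjusted p = 0.0289 with an estimated correlation). Among the higher members were Dbp at 1.08 ± 0.25, Per3 at 0.69 ± 0.13 and Tef at 0.67 ± 0.12, which are driven by the clock's positive arm. Arntl, which belongs to that positive arm and was named after its values were seen, fell by 0.48 ± 0.12 (adjusted p = 0.00197). Cry1, a list member outside that arm that was also named after its values were seen, had -0.24 ± 0.08 (adjusted p = 0.028). Of 22 endoplasmic reticulum stress genes 5 rose, the same count adjusted over the list alone, with the chaperone Hspa5 at 0.38 ± 0.09 and Creld2 at 0.68 ± 0.16 (camera adjusted p = 0.00141, adjusted p = 0.313 with an estimated correlation). Of 28 ribosomal protein genes 16 fell, 20 adjusted over the list alone, such as Rpl3 (-0.25 ± 0.05), with a camera adjusted p of 6.7e-13 (adjusted p = 0.0503 with an estimated correlation). Reads of ribosomal protein genes can be shared with near-identical copies. Among the 21 members with no tested pseudogene copy of the same name 14 fell, and among the 7 with 1 or more 2 fell. Their medians were -0.17 and -0.18. Copies under other names or below the expression minimum were not counted, so the 21 may share reads too.

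Members of 3 immune lists fell in liver and none of them rose. These were 6 of 17 interferon response genes, such as Bst2 (-0.42 ± 0.09) and Irf7 (-0.54 ± 0.14), with a camera adjusted p of 0.000599 (adjusted p = 0.363 with an estimated correlation). They were also 4 of 21 acute phase genes, with the fibrinogen chains Fga (-0.43 ± 0.10) and Fgg (-0.43 ± 0.10) among them (camera adjusted p = 0.0227, adjusted p = 0.557 with an estimated correlation). Of 18 macrophage markers 2 fell, Mpeg1 (-0.37 ± 0.12) and Ctss (-0.29 ± 0.09), with a camera adjusted p of 0.0182 (adjusted p = 0.481 with an estimated correlation). Counts adjusted over the list alone were the same for these 3 lists. Of 6 female-biased genes 2 fell, 3 adjusted over the list alone, including Gstt3 (-0.46 ± 0.14; camera adjusted p = 0.0495, adjusted p = 0.296 with an estimated correlation), and of 16 male-biased genes none passed (camera adjusted p = 0.709). Of 14 immediate early genes 1 fell, 2 adjusted over the list alone (camera adjusted p = 0.0134, adjusted p = 0.457 with an estimated correlation). The endothelial, stellate cell, erythrocyte, matrix, electron transport and mitochondrially encoded lists did not pass, with camera adjusted p from 0.106 to 0.951. Median, mean and test differed in sign in liver for the matrix list (median 0.03, mean -0.0031, test up) and the mitochondrially encoded list (-0.05, 0.0028, up). They also differed for the electron transport (0.0068, -0.0084, down), stellate cell (0.0071, -0.013, down) and erythrocyte lists (-0.11, 0.017, down). Outside the lists, the deiodinase Dio1 (1.01 ± 0.19), the heme synthesis enzyme Alas1 (0.97 ± 0.17), the secreted protein Tsku (0.95 ± 0.17) and the urinary protein Mup14 (0.91 ± 0.29) rose. The hepcidin paralog Hamp2 (-1.77 ± 0.50) and the trefoil factor Tff3 (-1.53 ± 0.43) fell. Mup14 and Hamp2 have close paralogs that can share reads, so their values are uncertain.

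In liver 1012 of 11335 tested genes differed by diet, 430 higher and 582 lower (limma, adjusted p under 0.05), and 79 of them by a fold of at least 1.5. With TPM as deposited the count was 57, with 9 higher and 48 lower, and without the 26 libraries of low scale factor it was 1525, with 723 higher and 802 lower. Without mouse 80, whose liver library held muscle genes, the count was 1223, with 567 higher and 656 lower.

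The third comparison asked the same in muscle. Of 25 genes of fatty acid oxidation 14 rose on the high-fat diet, and of 20 genes of fatty acid synthesis 6 fell and 1 rose. The synthesis list lost its call with an estimated correlation (adjusted p = 0.265), and the oxidation list kept it (adjusted p = 4.6e-05). Plin5, a coat protein that joins lipid droplets to mitochondria, rose from 11 ± 6.57 to 20.8 ± 9.54 scaled TPM (SD, n = 74 and 75), a log2 fold change of 0.93 ± 0.11 (SE; adjusted p = 6.62e-10, limma, 68 of 75 mice above the control median). BC048679 (ENSMUSG00000061877) had the largest rise among the genes named by the rule, 1.72 ± 0.23 (adjusted p = 1.33e-08, 70 of 75 mice). Fasn fell from 76.2 ± 175 to 16.7 ± 15.8 scaled TPM (-1.16 ± 0.23, adjusted p = 0.000701, 66 of 75 mice not above the control median).

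Of 25 fatty acid oxidation and PPAR alpha target genes in muscle 14 rose, 21 adjusted over the list alone, and none fell (camera adjusted p = 3.36e-37, adjusted p = 4.6e-05 with an estimated correlation). The thioesterases Acot1 (1.02 ± 0.13) and Acot2 (0.57 ± 0.10), the dehydrogenase Acadl (0.48 ± 0.07), the reductase Decr1 (0.38 ± 0.06), the isomerase Eci2 (0.37 ± 0.05), Angptl4 (0.88 ± 0.21) and Pdk4 (0.62 ± 0.15) were among them. Ucp3, the mitochondrial uncoupling protein of muscle, had 0.27 ± 0.12 and did not pass (adjusted p = 0.364). Of 20 fatty acid synthesis genes 6 fell and 1 rose, or 9 and 1 adjusted over the list alone (camera adjusted p = 1.87e-06, adjusted p = 0.265 with an estimated correlation). The lower members included Thrsp, a lipogenic regulator (-1.09 ± 0.22), Acaca (-0.96 ± 0.16), the citrate lyase Acly (-0.86 ± 0.18) and the elongase Elovl6 (-0.85 ± 0.21), and the member that rose was the glycerol phosphate acyltransferase Gpam (0.39 ± 0.05). Muscle libraries also held adipocyte transcripts, with Cfd, the adipocyte protease adipsin, at 204 ± 209 scaled TPM in control and 94.3 ± 95.2 in high-fat mice (-0.98 ± 0.28, adjusted p = 0.0543). None of 18 adipocyte markers passed in muscle, 1 was lower adjusted over the list alone, and their median was 0.04 (camera adjusted p = 0.864).

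Clock genes also moved in muscle, with 5 of 17 up and 1 down, or 8 and 1 adjusted over the list alone. Dbp (0.56 ± 0.14), Ciart (0.55 ± 0.11) and Hlf (0.27 ± 0.07) rose and Arntl (-0.39 ± 0.08) fell. The clock list had a camera adjusted p of 0.000132 (adjusted p = 0.0683 with an estimated correlation), and its median was 0.10, or -0.11 with TPM as deposited, where that of all genes was -0.15. Slow fibre genes had a median of 0.44 and fast fibre genes a median of -0.21, and 0 of 13 and 0 of 17 members passed by limma over all genes or over the list alone. Examples are the slow troponin Tnni1 with 0.77 ± 0.35 (adjusted p = 0.346) and the fast myosin Myh4 with -0.27 ± 0.13 (adjusted p = 0.372). The camera adjusted p was 3.79e-05 for slow fibres and 4.73e-05 for fast fibres (adjusted p = 0.346 and adjusted p = 0.414 with an estimated correlation). No member passed over all genes in the macrophage (22 tested, such as Trem2 with 0.50 ± 0.15), matrix (28), endoplasmic reticulum stress (19) and interferon (12) lists of muscle. Their camera adjusted p were 1.5e-06, 2.12e-07, 1.5e-06 and 0.000385 in that order. Their adjusted p with an estimated correlation were 0.269, 0.265, 0.163 and 0.265. Their medians were 0.18, 0.13, 0.12 and -0.12, and with TPM as deposited 0.02, -0.05, -0.05 and -0.21. That of the oxidation list was 0.31, and 0.09 with TPM as deposited. Adjusted over the list alone, 3 macrophage genes and 3 stress genes were higher, 1 interferon gene was lower, and no matrix gene passed. Hspa5 in muscle had 0.21 ± 0.06 (adjusted p = 0.0635), and 0.16 (adjusted p = 0.0218) without mouse 80. Of 28 ribosomal protein genes 1 fell, Rps4x (-0.13 ± 0.04), and 3 adjusted over the list alone (camera adjusted p = 2.15e-06, adjusted p = 0.265 with an estimated correlation), and such genes can share reads with near-identical copies. The insulin signalling list did not pass (camera adjusted p = 0.864), with a median of -0.04, a mean of 0.02 and a test direction of down, and the atrophy list had a median of 0.02, a mean of -0.0092 and a test direction of down (camera adjusted p = 0.94). The insulin signalling member Tbc1d1, a regulator of glucose transporter traffic, rose by 0.43 ± 0.11, and Slc2a4 had -0.25 ± 0.10 (adjusted p = 0.255). The electron transport list had 0 of 30 members past the threshold and a camera adjusted p of 0.00609 (adjusted p = 0.731 with an estimated correlation), and the erythrocyte list 0 of 7 and 0.0344 (adjusted p = 0.265 with an estimated correlation). None of 23 cholesterol synthesis genes passed in muscle (camera adjusted p = 0.68). Outside the lists, Mss51 (1.00 ± 0.27) and the mitochondrial carrier Slc25a34 (0.84 ± 0.11) rose, and the transketolase Tkt (-0.59 ± 0.16) and the kinase Pak1 (-0.49 ± 0.10) fell, Tkt with an adjusted p of 0.0456 that became 0.05004 under another scaling. Of the 25 called muscle genes printed here, 18 stayed called with no filter and 18 without the libraries of lowest coding share.

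In muscle 89 of 13218 tested genes were higher on the high-fat diet and 54 lower (limma, adjusted p under 0.05), and 17 of them by a fold of at least 1.5. Without mouse 80, whose liver and muscle libraries carry each other's genes, 223 differed, 140 higher and 83 lower, and with TPM as deposited 15 differed, 5 higher and 10 lower, while the median of all genes moved to -0.15. Across tissues the set test with a preset correlation called 7 of 11 lists in adipose tissue, 13 of 23 in liver and 12 of 21 in muscle. Without mouse 80 the gluconeogenesis and female-biased lists of liver lost their call (adjusted p = 0.0571 for both), as did the electron transport and erythrocyte lists of muscle (adjusted p = 0.0529 for both), and the mitochondrially encoded list of muscle gained one (adjusted p = 0.0381). The calls in liver were 12 with median-of-ratios scaling and 10 without libraries of low scale factor. Only 1, 3 and 1 of the calls held with an estimated correlation, and on simulated data the preset correlation called unchanged lists. The simulated lists were raised by 0.5 on the log2 scale. A lost call of a list with a smaller or mixed shift therefore does not show that the list was unchanged.

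**Figure D2:**
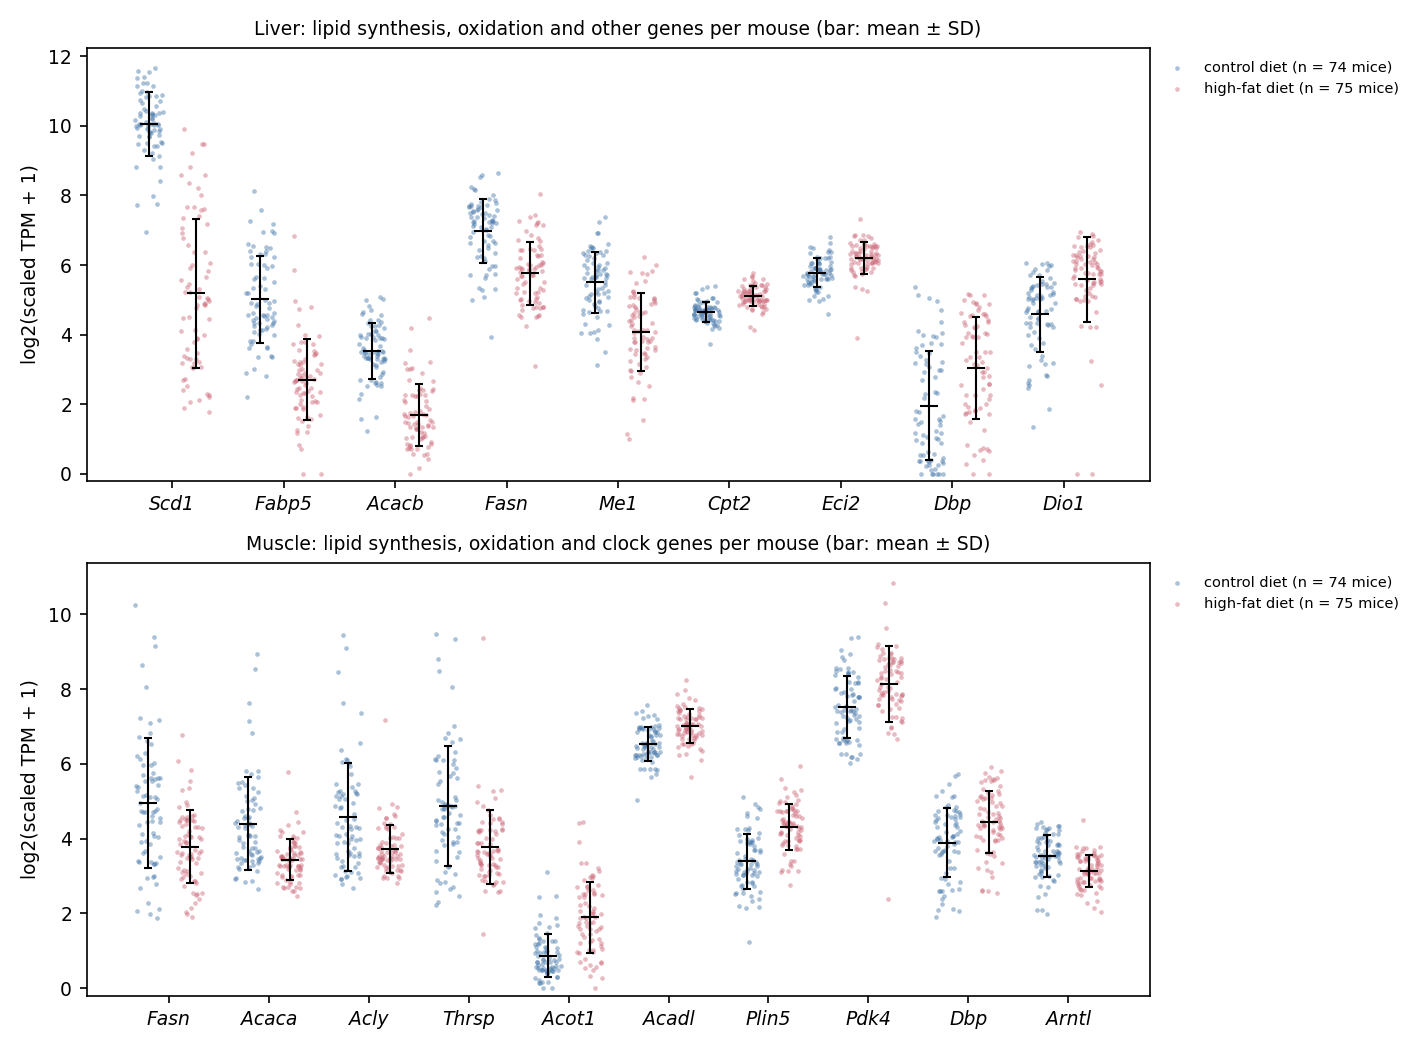
Each point is 1 mouse and gives log2(scaled TPM + 1) of 1 gene in liver (upper panel) or muscle (lower panel), with control mice in blue, high-fat mice in red and black bars for the mean and SD. In liver Scd1 fell by 4.87 on the log2 scale and spread widely among the high-fat mice, and in muscle a few control mice held high levels of Fasn, Acaca, Acly and Thrsp.

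**Figure D3:**
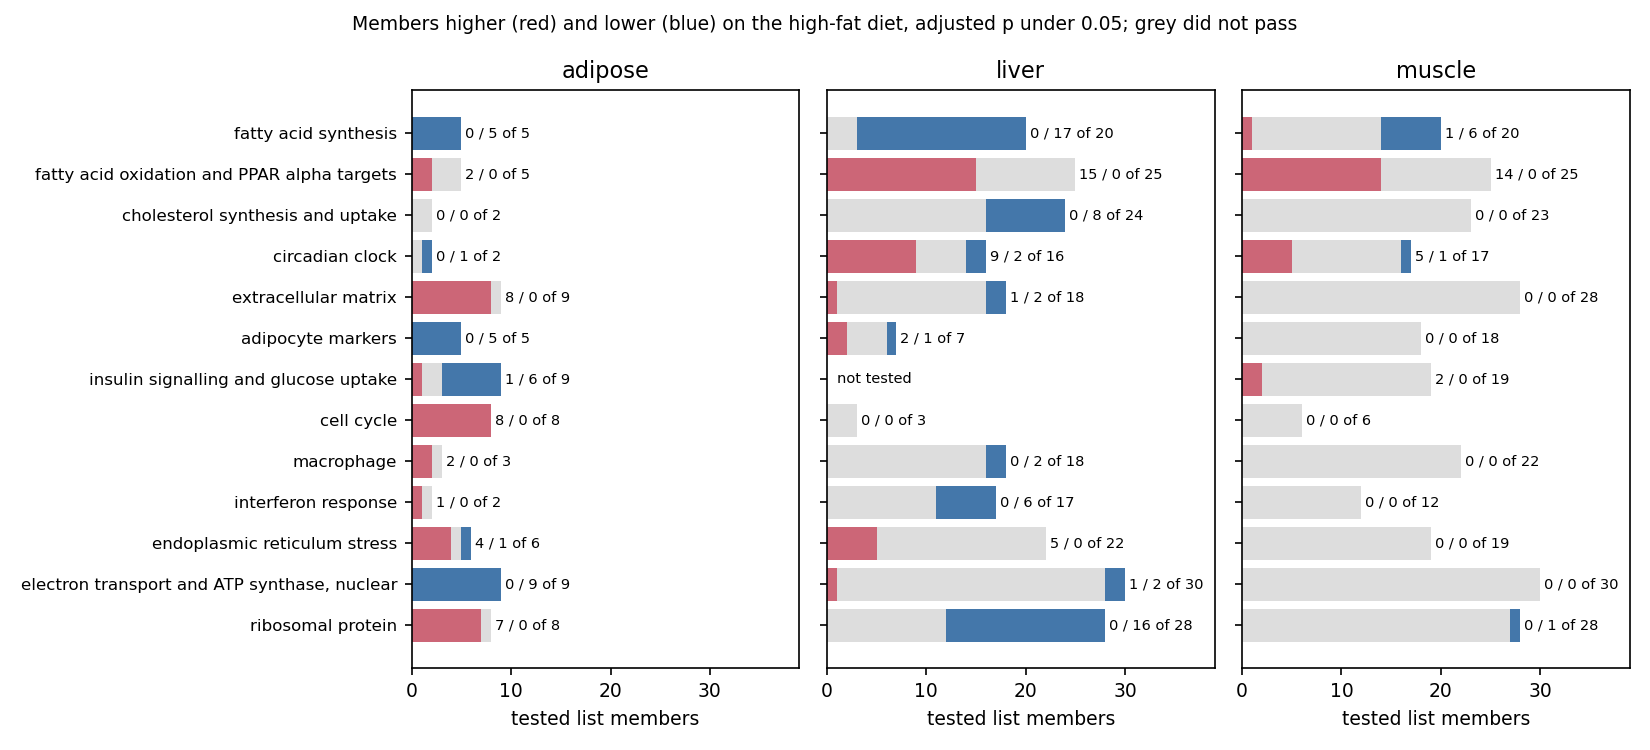
Bars give the number of tested members of each gene list in adipose tissue, liver and muscle, with members higher on the high-fat diet in red, lower in blue and not past the threshold in grey, and numbers give higher / lower of tested. Fatty acid synthesis had 5 of 5, 17 of 20 and 6 of 20 members lower, and fatty acid oxidation 2 of 5, 15 of 25 and 14 of 25 higher.

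Calls were compared between tissues, with the limit that the same mice gave all tissues. Liver and muscle shared 35 genes higher in both and 13 lower in both, where independent lists would share 2.63 and 2.01, and 1 was higher in liver and lower in muscle and 2 the reverse (1.65 and 3.19 for independent lists). Liver and adipose tissue shared 17 genes higher and 32 lower in both (13.9 and 23.8 for independent lists), while 16 were higher in liver and lower in adipose tissue and 30 the reverse (15.7 and 21.1 for independent lists). Muscle and adipose tissue shared 8 higher and 3 lower (4.52 and 0.966 for independent lists), and 5 were higher in muscle and lower in adipose tissue and 0 the reverse (4.83 and 0.903). Among 1625 genes tested in all 3 tissues, 7 were called in each, and they are named here after their values were seen. Acaca fell in all 3, Angptl4, the acyl-CoA synthetase Acsl1 and Adap2 rose in all 3, and Agpat3, Ccl9 and Hlf moved in different directions. Hlf, a clock output gene, fell by 0.52 ± 0.11 in adipose tissue and rose by 0.27 in muscle.

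The next comparison tested whether the diet effect itself differed between tissues. Between liver and adipose tissue it differed for 368 of 1695 genes, 150 with a higher effect in liver and 218 with a lower one (limma interaction, adjusted p under 0.05). Ccl9 fell by 0.50 ± 0.09 in liver and rose by 1.45 ± 0.16 in adipose tissue, a difference of -1.95 ± 0.19 (adjusted p = 1.24e-18). Pltp, the phospholipid transfer protein, fell by 0.45 ± 0.10 in liver and rose by 0.76 ± 0.09 in adipose tissue (difference -1.24 ± 0.15), and Por moved the other way, up in liver and down in adipose tissue (0.79 ± 0.18). Between liver and muscle the effect differed for 304 of 10210 genes, 100 higher and 204 lower in liver, and the lower ones included Scd1 (-4.19 ± 0.40), Fabp5 (-2.42 ± 0.27), Acacb (-1.92 ± 0.16) and Me1 (-1.29 ± 0.18). Scd1 in muscle had -0.71 ± 0.29 (adjusted p = 0.274). Alas1 (0.89 ± 0.19) and Fitm1 (0.94 ± 0.20) had a higher effect in liver than in muscle. Between muscle and adipose tissue it differed for 400 of 1900 genes, 171 higher and 229 lower in muscle, with Cd68 at -1.28 ± 0.22, Retn at 1.202 ± 0.32 and Hsd11b1 at 1.06 ± 0.21. With TPM as deposited the higher and lower counts were 2 and 79, 1 and 5, and 3 and 442 for the 3 pairs in that order.

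The design's interest in variability among mice was addressed by testing whether the spread around the diet median differed. In liver 2 of 6041 genes differed, both wider on the high-fat diet. The SD of Scd1 on the log2 scale was 0.91 in control and 2.15 in high-fat mice (adjusted p = 7.34e-07), and that of Obp2a 1.29 and 2.23 (adjusted p = 0.000897). Obp2a averaged 2.85 scaled TPM in control and 25.9 in high-fat liver, and the log2(scaled TPM + 1) scale narrows spread at low levels. Its wider spread therefore cannot be separated from its higher mean. With a pseudocount of 0.5 only 1 liver gene differed. In muscle 1 of 8220 genes differed, the citrate lyase Acly, whose SD was 1.44 in control and 0.65 in high-fat mice (adjusted p = 0.00895). Acaca in muscle had 1.25 and 0.55 (adjusted p = 0.0503). In adipose tissue 43 of 1828 genes differed, 37 wider and 6 narrower, but 24 differed without libraries of low scale factor and 0 with TPM as deposited. In liver 1 gene and in muscle 0 differed with TPM as deposited. The lysosomal peptidases Scpep1 (SD 0.30 and 0.56) and Ctsa (0.37 and 0.64) and the endothelial phosphatase Ptprb (0.29 and 0.48) were wider, and the small heat shock protein Hspb7 (1.16 and 0.72) and Acaca (0.98 and 0.61) were narrower. At an unadjusted p under 0.05 the counts were 241 in adipose tissue, 216 in liver and 408 in muscle. On simulated data a doubled spread was recovered for 26 of 67 genes in liver, 50 of 67 in muscle and 65 of 67 in adipose tissue, and without mouse 80 the muscle count was 3.

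Relations across mice were computed within each diet, 6 of a planned family of 12, because the others needed Lep. Scores are means of list members in SD units. The adipose macrophage score, of Adgre1, Cd163 and Cd68, rose with the liver lipid droplet score in control mice (Pearson r = 0.387, permutation p = 0.00097, adjusted p = 0.00194; Spearman rho = 0.441, permutation p = 0.00015, adjusted p = 3e-04; n = 73). In high-fat mice r was 0.464 (permutation p = 3e-05, adjusted p = 9e-05) and rho 0.572 (permutation p = 1e-05, the smallest these permutations can give; adjusted p = 3e-05; n = 75). Without the 2 mice farthest from the median of the macrophage score r was 0.346 in control and 0.481 in high-fat mice. With TPM as deposited this relation ended in both diets (r = -0.0476, permutation p = 0.69 in control and 0.0877, permutation p = 0.455 in high-fat mice), and with median-of-ratios scaling it was unchanged (r = 0.388 and 0.466). In control mice the macrophage and lipid droplet scores also followed the coding share (rho = 0.27 and 0.307), and in high-fat mice the values were 0.141 and 0.229. A first principal component in place of the mean gave r = 0.102 in high-fat mice, and 0.402 once mouse 80 was also left out. Slc2a4 in adipose tissue fell with the adipose macrophage score, with r = -0.305 in control mice (permutation p = 0.00884, adjusted p = 0.0133; rho = -0.338, permutation p = 0.00358, adjusted p = 0.00537) and r = -0.592 in high-fat mice (permutation p = 1e-05, adjusted p = 6e-05; rho = -0.577, permutation p = 1e-05, adjusted p = 3e-05). Without the 2 mice farthest in Slc2a4 r was -0.347 and -0.545. The relation of Slc2a4 turned to r = 0.701 and rho = 0.332 in control mice with TPM as deposited. In high-fat mice r was then 0.403, but rho was -0.152 (permutation p = 0.192) and r without the 2 farthest mice 0.136. Slc2a4 and this score come from the same library and share its factor when unscaled, so TPM as deposited cannot decide whether the relation holds. With median-of-ratios scaling r was -0.321 and -0.6. Slc2a4 followed the coding share with rho = -0.276 in control and 0.0689 in high-fat mice. The adipose macrophage score showed no relation past the threshold with the liver macrophage score in control (r = -0.0849, permutation p = 0.471, adjusted p = 0.566; rho = -0.0808, permutation p = 0.494) or high-fat mice (r = 0.0571, permutation p = 0.629, adjusted p = 0.629; rho = 0.0108, permutation p = 0.927). No batch is given in the labels, so no within-batch value could be had.

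**Figure D4:**
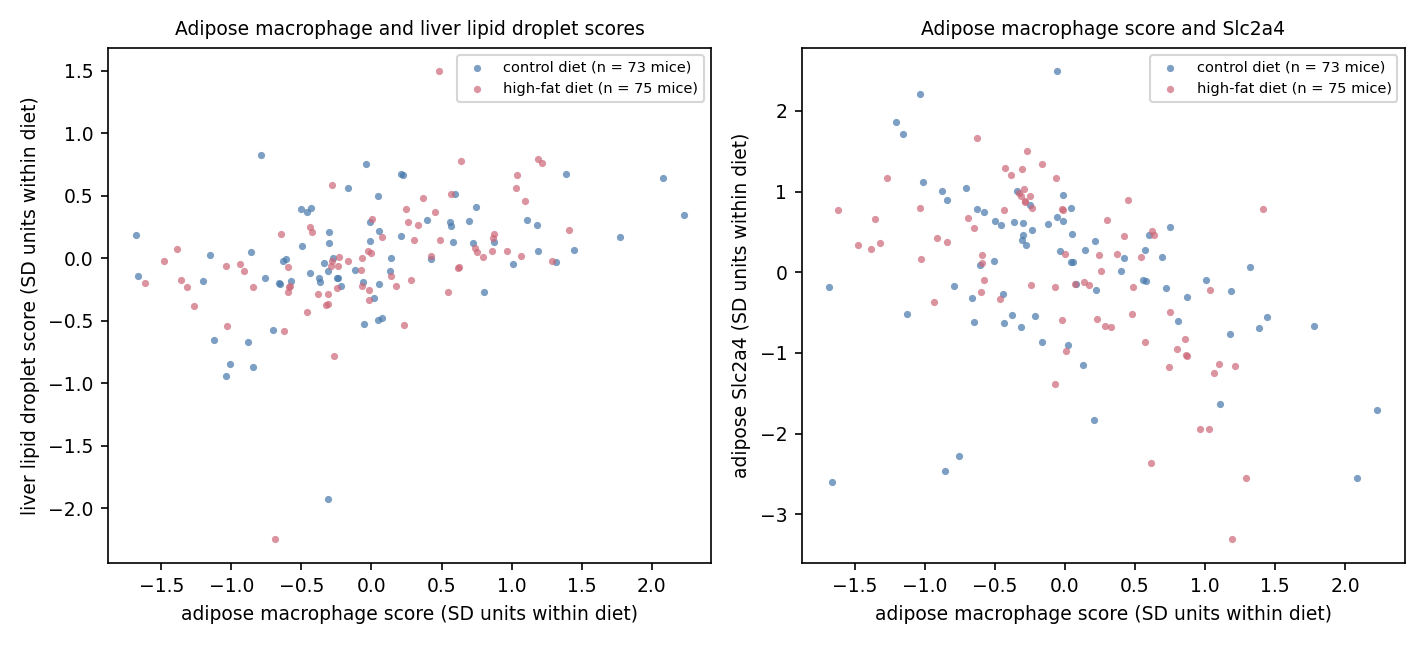
Each point is 1 mouse, with control mice in blue and high-fat mice in red, and the x axis of both panels is the adipose macrophage score in SD units within the diet. The left panel gives the liver lipid droplet score (r = 0.387 and 0.464) and the right panel adipose Slc2a4 (r = -0.305 and -0.592), both in SD units within the diet.

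A clock score, chosen after the clock genes' values were seen, was formed in liver and muscle as the mean of 9 output genes minus the mean of 2 genes of the positive arm. Within a diet, the liver and muscle scores of the same mouse correlated, with r = 0.773 and rho = 0.757 in control mice (n = 74) and r = 0.742 and rho = 0.766 in high-fat mice (n = 75). Each had a permutation p of 1e-05 (adjusted p = 1e-05 for the 2 values of r), the smallest these permutations can give. Without the 2 mice farthest from the median of the liver score r was 0.731 and 0.725.

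**Figure D5:**
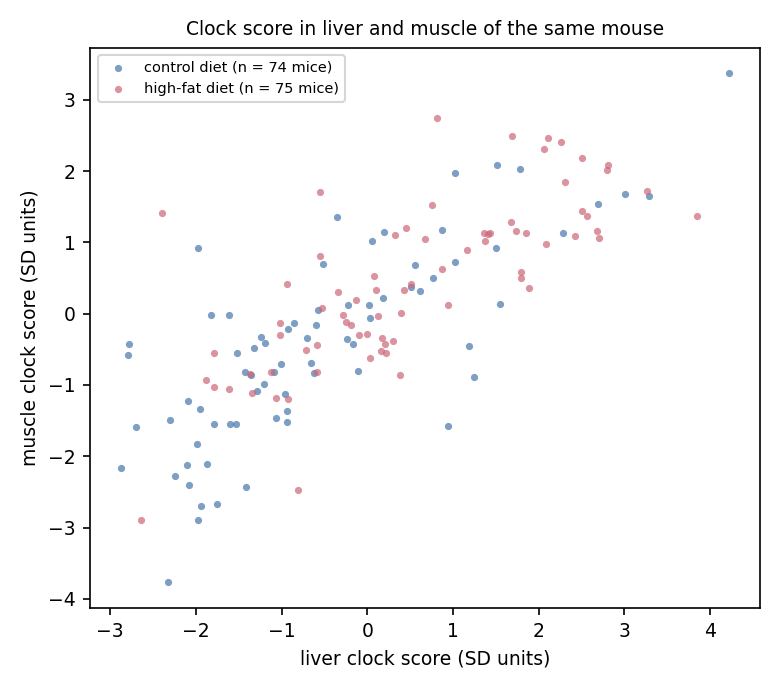
Each point is 1 mouse and gives the clock score of its liver (x axis) and of its muscle (y axis), in SD units over all mice, with control mice in blue and high-fat mice in red. The scores rose together in both diets (rho = 0.757 and 0.766).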

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

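The tests of cell type proportions, of the clock and of mouse 80 were chosen only after the results were seen, the test of the coding share was chosen after the files were read but before its result, and the counts of other splits of the samples were planned before. The diet effect differed between tissues by a test of the difference itself for 368 genes between liver and adipose tissue, 304 between liver and muscle and 400 between muscle and adipose tissue. Between liver and adipose tissue the effect was higher in liver for Hsd11b1 (1.06), Prodh (0.83), Acaca (0.82) and Por (0.79), and lower in liver for Ccl9 (-1.95), Pltp (-1.24), Cstb (-1.06) and Tcirg1 (-1.01). Between liver and muscle it was higher in liver for Fitm1 (0.94), Alas1 (0.89), Aldh3a2 (0.75) and Oat (0.67), and lower for Scd1 (-4.19), Fabp5 (-2.42), Acacb (-1.92) and Me1 (-1.29). Between muscle and adipose tissue it was higher in muscle for Retn (1.202), Hsd11b1 (1.06), Perp (0.83) and Prodh (0.81), and lower for Cd68 (-1.28), Adssl1 (-1.11), Cyba (-1.06) and Cd52 (-0.98).

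In adipose tissue 2 of 3 macrophage markers and 2 of 4 chemokines were higher and 5 of 5 adipocyte markers lower on the high-fat diet (no set test for the first 2 lists, and adjusted p = 0.106 with an estimated correlation for the last), which was weighed against a lower share of adipocytes with the other cell types in their former proportions. The macrophage markers rose by 0.867 ± 0.11 (SE) on the log2 scale and the adipocyte markers fell by 0.663 ± 0.0887, while the endothelial markers had -0.0817 ± 0.0493 and the lymphocyte markers -0.00225 ± 0.1. The macrophage markers rose by 0.914 ± 0.123 more than the 7 endothelial and lymphocyte markers (permutation p = 1e-05, the smallest these permutations can give), which argues against that explanation as the whole cause. With the coding share as a covariate 100% of the 14 called members stayed called, and 8 of 14 stayed called with TPM as deposited. The values given the covariate had already been scaled by a factor that follows the coding share (rho = 0.847 in adipose tissue). The covariate therefore cannot decide whether libraries that differ in that share play a part. A larger number of macrophages, and a higher level of these genes per macrophage, both remain open as effects of the diet.

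On the high-fat diet 9 of 16 clock genes were higher in liver and 5 of 17 in muscle, and Arntl was lower in both, while in adipose tissue Hlf fell by 0.52 (0.28 and 0.27 in liver and muscle) and none of 2 clock genes rose. The clock list had a camera p as small in 1 of 100 splits of the mice in liver and 2 of 100 in muscle, which argues against a clock phase that varies between mice without regard to diet. With the muscle score of the mouse held fixed, the diet difference of the liver score was 0.276 ± 0.17 SD units (p = 0.107), against 1.06 ± 0.246 without it. The score was built from genes already seen to change, and adipose tissue has only 2 tested clock genes. A diet effect on the clock and tissues of the 2 diets collected at different hours cannot be told apart, because the labels give no hours of collection.

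The liver and muscle libraries of mouse 80, on the high-fat diet, held the genes of another tissue. In its library labelled liver, hepatocyte genes took 0.0537% of TPM (other livers at least 6.03%) and muscle genes 17.5%, and in its library labelled muscle hepatocyte genes took 8.54%. A mixture of both tissues would leave hepatocyte genes a larger share than that. With the labels exchanged, the deviations of its libraries correlated at 0.407, against 0.231 for the best other mouse and 0.0885 as labelled. Among mice that matched, the median was 0.788, and the highest value between different mice was 0.446, above 0.407. Exchanged labels are the candidate explanation from the tissue genes, and the correlation alone does not settle it. No biological explanation was tested.

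Other splits of the same samples into groups of the real sizes, 100 with the real one included, were counted for each result. For the diet effect the real split called 1001 genes in adipose tissue, 1012 in liver and 89 higher with 54 lower in muscle. The highest other split called 21, 2 and 0, and 1 of 100 splits reached the real count each time. That is the smallest share these splits can give, and it makes chance unlikely for these counts. Control mice carry numbers up to 75 and high-fat mice numbers from 76. A difference that follows the numbering cannot be told apart from the diet, and random splits do not test for it. For the differences between tissues the highest other splits called 0 genes between liver and adipose tissue, 1 between liver and muscle and 58 between muscle and adipose tissue. Again 1 of 100 reached the real count each time, which makes chance unlikely here too. For the spread the real split called 43 genes in adipose tissue, 2 in liver and 1 in muscle, the highest other split 0, 1 and 1, and 1, 1 and 3 of 100 reached the real count. Chance is unlikely for the adipose count. In liver and muscle the real counts lay 1 and 0 above the highest other split, so little rests on them.

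For gene lists, 5 of 100 splits called as many lists as the 7 of adipose tissue and 7 of 100 as many as the 12 of muscle, so chance cannot be excluded for those numbers of lists. In liver 2 of 100 splits called as many as the real 13, and the highest other split also called 13. The highest other splits called 7 lists in adipose tissue and 13 in muscle. Single lists differed in this respect. Fatty acid oxidation in liver and in muscle and fatty acid synthesis in liver and in adipose tissue had a p as small in 1 of 100 splits, as did the clock and ribosomal lists of liver and the adipocyte markers of adipose tissue. The fast fibre, slow fibre and matrix lists of muscle had one as small in 31, 17 and 11 of 100, and the interferon, acute phase and macrophage lists of liver in 20, 35 and 26 of 100. Among other called lists, fatty acid synthesis in muscle had one as small in 7 of 100 and cholesterol synthesis in liver in 12. The electron transport and ribosomal lists of adipose tissue had one as small in 9 and 29.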

How the results depend on the processing

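Tests chosen only after the data were seen were those with the coding share, unscaled TPM, a mean TPM of at least 5, a pseudocount of 0.1 or array weights, and those without libraries of low scale factor, unmatched mice or mouse 80. TPM give no depth, so what depth limits could not be measured. Not run for lack of counts were the count-based Wald test, limma-voom with and without the block, the total count as covariate, leaving out libraries of lowest total count and a count minimum of 20. With the replicate block of mouse number the differences between tissues numbered 386 (liver and adipose tissue), 305 (liver and muscle) and 455 (muscle and adipose tissue), and the block changed no call of the 24 named differences. With the planned scaling within each tissue they numbered 439, 298 and 450 for these pairs in that order. Of the named diet effects, 40 in adipose tissue, 44 in liver and 32 in muscle, 34, 43 and 25 were called. Of these calls 1 was lost under the planned median-of-ratios scaling and 12 without a filter (5 in liver, 7 in muscle). Leaving out the 10% of libraries of lowest coding share lost 8 (1 in liver, 7 in muscle). TPM as deposited lost 56, and 1 more reversed, so that 23, 12 and 10 calls were kept in adipose tissue, liver and muscle. Without mouse 80, all 43 calls in liver and all 25 in muscle were kept, and 2 of the 76 named effects there gained a call.

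The planned fold minimum of 1.5 gave 91 genes in adipose tissue, 79 in liver and 17 in muscle, and an adjusted p under 0.01 gave 532 in liver and 59 in muscle, fewer by construction. No filter gave 82 in muscle, where more genes were tested. With TPM as deposited the diet counts were 317, 57 and 15, the differences between tissues 81 (liver and adipose tissue) and 6 (liver and muscle), and the spread counts 0, 1 and 0 for adipose tissue, liver and muscle. Unscaled TPM, which moved the median of all adipose genes to 0.21, also turned Ptprb to 0.0599, the relation of Slc2a4 to the macrophage score to 0.701 (control) and 0.403 (high-fat, but rho = -0.152), and that of the macrophage score to the liver lipid droplet score to -0.0476 (control), and left 0.0877 (high-fat). Array quality weights gave 2149 genes in liver and 409 in muscle, and 626 (liver and adipose tissue) and 979 (liver and muscle) differences. Without libraries of low scale factor there were 1525 genes in liver, 501 differences between liver and muscle, and spread counts of 24 in adipose tissue and 2 in muscle. A mean TPM of at least 5 gave 224 (liver and adipose tissue) and 180 (liver and muscle) differences, with fewer genes tested. Muscle had 223 genes without mouse 80 and also without the 7 mice whose tissues did not match. Leaving out the 11 liver libraries with a second number, as planned, gave 1036 genes in liver. The muscle spread count was 4 with deviations from the group mean, 3 without mouse 80, 2 with the coding share as covariate and 0 without the 10% of libraries of lowest coding share. The liver spread count was 1 with a pseudocount of 0.5 and 7 with no mean minimum. camera with an estimated correlation called 1 list in adipose tissue, 3 in liver and 1 in muscle, and fry called 10, 10 and 3. The first principal component score gave r = 0.102 for the macrophage and lipid droplet scores in high-fat mice, and 0.402 without mouse 80. Except where the alternative itself changes the genes tested, the threshold or the libraries, the cause was not tested.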

Other observations

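The levels of many genes in liver and muscle of the same mouse rose and fell together within the diets. In all 1171 of 10210 genes correlated positively past the threshold (Spearman, adjusted), 210 of them with rho over 0.5, and 63 correlated negatively, while the highest of 99 random pairings of mice gave 1 gene. Genes named here were chosen after their values were seen. The splicing factor Cwc22 had rho = 0.869, the ribosomal protein gene Rps12 0.853, the ferritin receptor Ncoa4 0.799 and the histocompatibility gene H2-T22 0.768. Rps12 can share reads with near-identical copies, so its value is uncertain. By list, the median rho was 0.502 for erythrocyte markers (4 of 6 called), 0.398 for the circadian clock (12 of 16) and 0.294 for the interferon response (8 of 10), against 0.0295 for fatty acid synthesis (1 of 19) and 0.00562 for cholesterol synthesis (0 of 23). Between liver and adipose tissue 150 of 1695 genes correlated positively, and between muscle and adipose tissue 228 of 1900.

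Some ribosomal protein genes and their annotated pseudogene copies moved in opposite directions across mice, and others did not. Of 31 such pairs in liver 16 had rho below -0.3, and of 32 in muscle 13, while the highest of 99 shuffles gave 0 in each tissue. Among the most negative, Rpl19 and its copy Rpl19-ps11 had rho = -0.889 in liver and -0.865 in muscle, Rps12 and Rps12-ps3 -0.723 and -0.68, and Rps2 and Rps2-ps13 -0.727 and -0.661. The most positive pair, Rpl28 and Rpl28-ps1 in muscle, had rho = 0.58 (0.0961 in liver). Such a gene and its copy can share reads. These values therefore cannot tell opposite expression from reads assigned differently between mice, and the shuffles do not test for it.

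Single adipose libraries held genes of other organs. Pbsn, the prostate protein probasin, reached 3140 scaled TPM in 1 mouse on the high-fat diet and 935 in 1 on the control diet, and the next highest value was 0.887. Mb, muscle myoglobin, reached 2130, 641 and 221 in 3 mice, against a median of 0.257. Of the 7 mice whose liver and muscle did not match, the muscle of mouse 45 (control) correlated with the liver of a high-fat mouse at 0.490, and the livers of 3 high-fat mice with the muscles of the control mice 17, 72 and 33 at 0.534, 0.538 and 0.479. Mice 17, 72 and 33 were among the mice that matched. The 3 livers held 2.64%, 2.40% and 4.15% of TPM on nuclear protein-coding genes (high-fat liver median 60.6%). The muscle of mouse 45 held 35.1% (control muscle median 66.3%). In the pairing check over 150 genes the first liver again correlated best with mouse 17 (0.507). The others correlated best with other muscles, at 0.221 and 0.274. All 4 matches cross the diets, which leaves the diet of these libraries in doubt but does not show it to be wrong. Their labels were kept, and an alternative left out the 7 mice. Among the mice that matched, liver and muscle of the same mouse correlated at a median of 0.788, and the highest value between different mice was 0.446.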
